A study of Mus musculus with 18 samples.

How the data were processed

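RNA was measured in mouse embryonic limb buds of 6 groups with 3 libraries each, 18 libraries in all. Per the labels, the groups were CD1 forelimb at e10.5, CD1 hindlimb at e11.0, and hindlimbs of Pitx1 wild type (BALB/c) and Pitx1 null embryos at e11.0 and at e11.5. Embryos came from timed breedings and total RNA was purified on silica spin columns, per the labels' protocols. The e10.5 and e11.0 libraries were made by ribosomal RNA depletion with strand kept, and the e11.5 libraries by mRNA enrichment, per the labels. Replicates 1 and 2 of every group were sequenced in run 3982. Replicate 3 came from run 3412 at e11.0 and from run 126, an unstranded library, at e11.5, while the titles name no run for replicate 3 of the CD1 groups. The labels do not say that replicates came from separate litters or pools, so p-values measure only the spread between these samples, which may be technical.

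The deposited data were 3 tables, 1 per comparison, and levels in different tables were normalized separately. Reads were aligned with STAR and counted per gene with featureCounts against GRCm38 (mm10), and edgeR was used, per the submitters' processing notes. Versions, settings and whether counting used strand were not given in the sources used here, so an antisense gene cannot be told apart from its partner. The authors gave each library's expression as CPM, read counts scaled to the total on the genes listed, and each CPM column sums to 1000000. The authors' deposited log2 fold change and average log2 CPM stand beside it, per the file headers. A likelihood-ratio score, an unadjusted p-value and an adjusted p-value from edgeR were also deposited by the authors, per the file headers. The tables list 13540 genes for CD1, 14027 for e11.0 and 13478 for e11.5, and every listed gene exceeded 0.5 CPM in at least 3 libraries, so genes below that level were not analysed here. Gene identifiers matched GENCODE release M 21 for 13519, 14004 and 13463 of them, and this annotation gave symbols and GRCm38 coordinates. Symbols turned into dates numbered 20, 19 and 20 in the deposited files, and these genes were taken by identifier.

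The CPM values were whole multiples of the worth of 1 read, within 0.01 read, for 100% of values in each library. The implied depth on listed genes was 24.5 to 45 M reads (M, 1000000) in the CD1 libraries, 17.4 to 44.2 M at e11.0 and 30.2 to 53.6 M at e11.5. At these depths 1 read was worth at most 0.0575 CPM. Reads without molecular identifiers are not independent molecules, and these depths speak of counting error only. A search among the lowest values alone found whole reads in only part of the libraries. The implied reads were used for depth alone, and no count test was run on them. Because the tables hold CPM, the test planned for counts was replaced by the one planned for CPM, and the authors' deposited adjusted p served as the count-based alternative.

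Each table was fitted alone with limma 3.58.1 in R 4.3.3, on log2(CPM + 1) with a mean-dependent prior (limma-trend), with terms for the group and for the run (run 3982 against the other). This left 3 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all listed genes and a threshold of 0.05. A fold change on the log2(CPM + 1) scale understates the change of genes of low level. Levels are given as mean CPM ± SD, log2 fold changes with their standard error (SE). A principal component analysis of each table had a first component, holding 80.2%, 66.2% and 75.6% of the variance, that parted replicate 3 from replicates 1 and 2. The second, with 13.9%, 22.8% and 15.8%, parted the compared groups. Same-numbered libraries of the compared groups deviated together from their group means. The correlations across genes for replicates 1, 2 and 3 were 0.73, 0.85 and 0.95 in CD1, 0.76, 0.71 and 0.88 at e11.0, and 0.76, 0.86 and 0.93 at e11.5. Between replicates 1 and 2 of the compared groups they were 0.81 and 0.9 in CD1, 0.59 and 0.44 at e11.0 and 0.66 and 0.65 at e11.5. Each same-numbered correlation was over 0.1, so a fit with the replicate number as a block was run, but the values also show the shared run, and in CD1 they do not tell replicates 1 and 2 apart. The blocked value is given where it changes the call of a gene discussed in the text, but only for some counts of list members. At e11.0, for example, the block also called Ror2, Aurka, Mki67 and Pbx2 lower and Id1 higher, and the list counts leave these out.

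Fixed lists of genes, 27 in all, were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 27 lists in each comparison, and again with the correlation estimated from the libraries. They covered hindlimb identity, forelimb identity, anterior Hox genes, posterior HoxA and HoxD genes, the apical ectodermal ridge, the Shh pathway, the Bmp pathway, Fgf response, Wnt response, proximal and retinoic acid genes, anterior limb bud mesenchyme, and limb patterning and connective tissue factors. Further lists covered cartilage, tendon, the developmental stage, the cell cycle, hypoxia and glycolysis, immediate early genes, embryo sex and the neighbours of Pitx1. Markers of other cells that a dissected limb bud can hold made up the lists for muscle precursors, erythroid cells, endothelium, nerve and Schwann cells, surface ectoderm, macrophages, and somite and trunk. None of these lists was chosen on the present samples. Lin28b was a member of both the limb patterning list and the stage list, so these lists are not separate evidence for it. The named genes were the measured members of the limb identity lists and up to 4 members of each list with the smallest adjusted p. To these were added, in each direction, the 8 genes with the largest change past the threshold, with a mean of at least 1 CPM and no overlap between the groups, leaving out unnamed gene models and the sex genes. Some genes that meet this rule are not reported here.

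The overlap of calls between e11.0 and e11.5 was tested with Fisher's exact test in each direction. Genes called in CD1 with an absolute log2 fold change of at least 1 formed a hindlimb-higher set and a forelimb-higher set, with Pitx1 left out, and these were tested in the Pitx1 comparisons with camera, and with Fisher's exact test for overlap with the calls. Calls within 20 Mb of Pitx1 were compared with the rest of the genome by Fisher's exact test. The difference between the Pitx1 effects at e11.0 and e11.5 was not tested, because the plan tested it on counts only. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. The alternatives were other scalings of CPM, another pseudocount, a filter on low CPM, no run term, the replicate block, stricter thresholds, 1 run alone and each library left out in turn. Added after the data were seen were the fits without abundant noncoding, mitochondrial and globin genes, 1 run alone for CD1 and e11.0, and the scalings for lists, sets, overlaps and windows.

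The fits were tested on simulated data with 200 changed genes in each design. Of genes changed by 1.5-fold, 68.7% were recovered in the 13540-gene CD1 design, 73.1% in the 14027-gene e11.0 design and 82.1% in the 13478-gene e11.5 design. Of genes changed by 4-fold, 100% were recovered in each, none with the wrong sign, and 7, 9 and 6 unchanged genes were called. All 5 shifted lists were called in each design, and 0, 0 and 1 unshifted lists were called. The simulated lists held random genes drawn independently of each other at a dispersion of 0.01. Genes of a real list can move together, with an estimated correlation of 0.932 for the erythroid list at e11.0. Simulated libraries were also drawn independently around a mean shared within each run, with no scaling difference or other deviation of a whole library. The simulation therefore does not give the error rate of the gene tests or the list tests on these libraries.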

Results

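The data describe gene expression in early mouse limb buds, the outgrowths of mesenchyme and covering ectoderm from which the limbs form. Forelimb buds at e10.5 and hindlimb buds at e11.0 of CD1 embryos were compared because these stages match in morphology. Hindlimb buds of embryos without Pitx1, a homeodomain transcription factor of the hindlimb, were compared with wild type at e11.0 and e11.5 to find the part of the hindlimb programme that depends on it. Each of the 6 groups had 3 libraries (n = 3), with 17.4 to 53.6 M reads on listed genes (M, 1000000). Levels are deposited CPM as mean ± SD, fold changes are on the log2(CPM + 1) scale with their SE, and adjusted p-values for genes come from limma.

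The CD1 comparison asked which genes set hindlimb buds apart from forelimb buds of matched morphology. Every forelimb library was at e10.5 and every hindlimb library at e11.0, so limb type and embryo age cannot be told apart in any of these differences. The hindlimb regulators Pitx1, Tbx4 and Isl1 and the HoxC genes Hoxc9, Hoxc10 and Hoxc11 were higher in hindlimb, while Tbx5, the T-box factor needed to start the forelimb bud, was nearly restricted to forelimb. Of 17 genes from the anterior part of the Hox clusters, which are active further forward along the body axis, 13 were lower in hindlimb. Of 9 muscle precursor genes 4, and of 11 genes of hypoxia and glycolysis 7, were also lower in hindlimb, and 4 of 13 erythroid genes were higher. None of these lists passed with an estimated correlation (camera adjusted p = 0.294 to 0.404), and when 1 library was left out the muscle and hypoxia counts were 2 to 5 and 3 to 11. Of 13540 genes, 795 differed by limma, 326 higher and 469 lower in hindlimb, and 75 of them by an absolute log2 fold change of at least 1 (29 higher and 46 lower).

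Pitx1 (ENSMUSG00000021506, chromosome 13, 55825051 to 55836192, minus strand, GRCm38) was at 0.352 ± 0.1 CPM in forelimb and 209 ± 22.5 CPM in hindlimb (log2 fold change 7.28 ± 0.07 SE, limma adjusted p = 9.83e-12). Tbx4, the hindlimb T-box factor (ENSMUSG00000000094, chromosome 11, 85886422 to 85916097), was at 5.81 ± 0.145 CPM in forelimb and 127 ± 11.7 CPM in hindlimb (4.23 ± 0.07, adjusted p = 6e-10). Tbx5 went the other way, from 103 ± 27.6 CPM in forelimb to 0.156 ± 0.237 CPM in hindlimb (-6.47 ± 0.20, adjusted p = 1.73e-07), and 1 hindlimb library listed it at 0. Isl1, a LIM-homeodomain factor of the early hindlimb field, rose from 1.22 ± 0.0782 to 14.2 ± 1.36 CPM (2.77 ± 0.10, adjusted p = 4.93e-07). Of the 7 measured hindlimb identity genes 6 were higher and 1 was lower in hindlimb, with the same count adjusted over the list alone (camera adjusted p = 1.41e-12, and adjusted p = 0.294 with an estimated correlation). Of the 5 forelimb identity genes 4 were lower in hindlimb, the same 4 by count adjusted over the list alone (adjusted p = 1.44e-06, and adjusted p = 0.354 with an estimated correlation), and Hoxc8 did not pass (0.20 ± 0.10, adjusted p = 0.292).

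**Figure D1:**
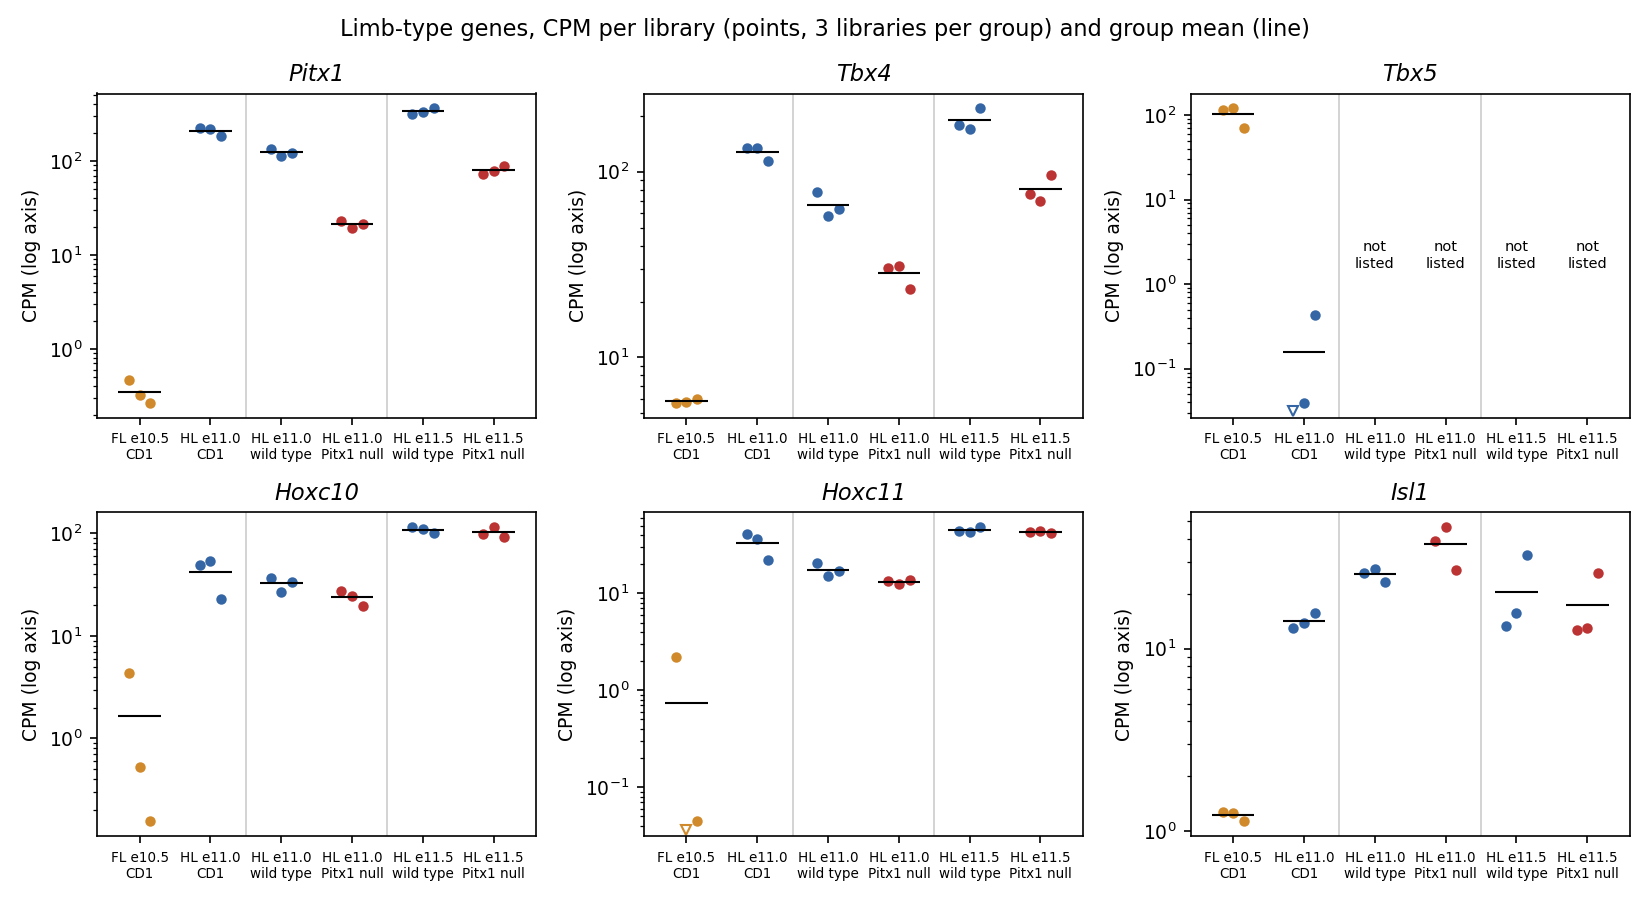
CPM of Pitx1, Tbx4, Tbx5, Hoxc10, Hoxc11 and Isl1 (log axis) in the 18 libraries, with points for libraries, lines for group means, and an open triangle at the bottom of the panel for a value of 0. Pitx1 was at 209 CPM in CD1 hindlimb against 0.352 CPM in CD1 forelimb and at 21.2 CPM in e11.0 null hindlimb against 124 CPM in wild type; levels can be compared only within each of the 3 tables, which grey lines separate.

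Hox genes, which pattern the body axis and the limb, differed in both directions. Hoxc10 was at 1.67 ± 2.30 CPM in forelimb and 41.9 ± 16.7 CPM in hindlimb (4.26 ± 0.34), with forelimb replicate 1 at 4.31 CPM, above the other forelimb libraries. Hoxc11 differed by 4.46 ± 0.32, Hoxc9 by 2.43 ± 0.14 and Hoxa13, a gene of the future hand and foot, by 1.93 ± 0.13. Of 17 measured anterior Hox genes 13 were lower and 1 was higher in hindlimb, or 14 and 1 adjusted over the list alone (adjusted p = 2.84e-14, and adjusted p = 0.354 with an estimated correlation). Hoxb2, Hoxb3 and Hoxb4 were lower by log2 values of -1.42, -1.45 and -1.56, and Hoxd8 by -1.10. Within the HoxC cluster Hoxc5 (-2.09 ± 0.15), Hoxc4 (-1.44 ± 0.12) and Hoxc6 (-0.81 ± 0.12) were lower in hindlimb. Of the 10 posterior HoxA and HoxD genes 5 were higher and 3 lower in hindlimb (6 and 4 adjusted over the list alone; adjusted p = 0.399). Hoxd9 and Hoxd10 were lower by -1.09 and -0.64, and Evx2, at the end of the HoxD cluster, was higher by 0.89.

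**Figure D2:**
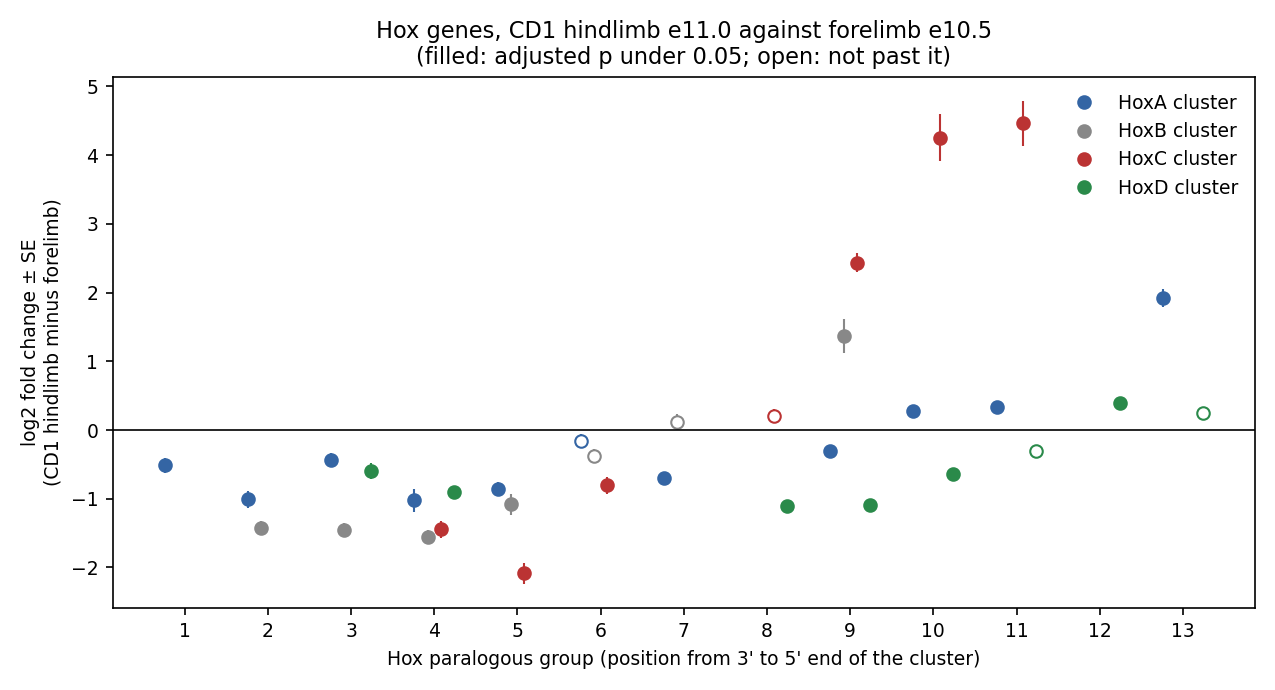
Log2 fold change of each measured Hox gene between CD1 hindlimb at e11.0 and CD1 forelimb at e10.5 (points, bars for SE, 3 libraries per group) against its paralogous group, coloured by cluster. Hoxc9, Hoxc10 and Hoxc11 lay at 2.43, 4.26 and 4.46, while Hoxb2, Hoxb3 and Hoxb4 lay between -1.42 and -1.56.

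Among the other genes of large difference, Rxfp1, a relaxin receptor, was at 0.0400 ± 0.0408 CPM in forelimb and 5.15 ± 2.13 CPM in hindlimb (2.51 ± 0.17). Lower in hindlimb were Gria2 (-2.21), a glutamate receptor subunit, Rspo4 (-1.82), a Wnt agonist, Runx2 (-1.76), a factor of bone formation, and Tgfb2 (-1.68), a growth factor. Of 8 measured genes of anterior limb bud mesenchyme 3 were lower in hindlimb, or 4 adjusted over the list alone, among them Pax1 (-1.39), Alx1 (-1.14) and Asb4 (-0.39). The camera adjusted p of this list was 0.00239, and adjusted p = 0.354 with an estimated correlation. Of 12 genes of the Shh pathway, the posterior signal of the limb bud, 6 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.404 with an estimated correlation). Shh itself rose from 5.78 ± 1.30 to 9.68 ± 2 CPM (0.66 ± 0.08) and Hand2, a factor of the posterior mesenchyme, by 0.43 ± 0.05, while Gli3, which represses Shh targets, differed by -0.45 ± 0.05. The Shh list no longer passed without forelimb replicate 1 (adjusted p = 0.189), and without hindlimb replicate 2 it held 3 higher genes.

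Of 9 measured muscle precursor genes 4 were lower in hindlimb and 0 higher, or 6 and 0 adjusted over the list alone (adjusted p = 0.000127, and adjusted p = 0.294 with an estimated correlation), with 2 lower without hindlimb replicate 1. Pax3 and Lbx1, which mark muscle precursors migrating into the limb, differed by -0.61 ± 0.07 and -0.55 ± 0.07. Of 11 genes of hypoxia and glycolysis 7 were lower in hindlimb, or 10 adjusted over the list alone (adjusted p = 6.5e-09, and adjusted p = 0.404 with an estimated correlation). Without forelimb replicate 1 or 2 the lower genes numbered 11 and 4, and without hindlimb replicate 1 or 2 they numbered 3 and 3. Vegfa, a signal for vessel growth, differed by -0.37, and Ldha, Pdk1 and Pgk1, enzymes of glucose metabolism, by -0.32, -0.58 and -0.27. Erythroid genes moved with these groups: 4 of 13 were higher in hindlimb, or 7 adjusted over the list alone (adjusted p = 0.000255, and adjusted p = 0.404 with an estimated correlation). The adult beta globins Hbb-bt and Hbb-bs, near-identical copies whose reads can be shared, rose by 1.5 ± 0.18 and 1.47 ± 0.20, and the embryonic Hbb-y by 0.40 ± 0.08. Without globin, mitochondrial and abundant noncoding genes the erythroid list did not pass (0.197).

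Of 18 limb patterning and connective tissue factors 2 were higher and 6 lower in hindlimb (2 and 8 adjusted over the list alone), with Sall1 at 0.82 ± 0.06 and Emx2 at -0.95 ± 0.10. Their adjusted p was 0.0418, with adjusted p = 0.404 with an estimated correlation and 0.0558 with the replicate block, where 3 genes were lower. In the apical ectodermal ridge list 1 of 11 genes, Trp63, was lower, against 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.404 with an estimated correlation). Trp63 was not called with the replicate block (adjusted p = 0.0859) and was called in 1 of 6 fits that left out 1 library. The ridge list held 0 lower genes without forelimb replicate 3 or any 1 of the hindlimb libraries. It did not pass without forelimb replicate 3 (0.179) or hindlimb replicate 3 (0.174), and the patterning list did not pass without replicate 2 or 3 of either group (0.0686 and 0.135 for forelimb, 0.0561 and 0.132 for hindlimb), and held 3 lower genes without forelimb replicate 3 or hindlimb replicate 2 or 3. Of 5 sex genes 1, Uty on the Y chromosome, was lower in hindlimb (3 adjusted over the list alone; adjusted p = 0.00872, and adjusted p = 0.404 with an estimated correlation). Uty was not called with the replicate block (adjusted p = 0.0662) and was called in 1 of 6 fits that left out 1 library; the list held 2 lower genes without forelimb replicate 1 and 0 without forelimb replicate 3 or any 1 of the hindlimb libraries. The stage list did not pass (adjusted p = 0.542), with 2 of 7 genes higher in hindlimb, Lin28a (0.56 ± 0.07) and Lin28b (0.47 ± 0.06), RNA-binding regulators of developmental timing (2 higher and 1 lower adjusted over the list alone). The other lists did not pass either, with adjusted p from 0.076 to 0.966. Lower in hindlimb were 3 of 12 genes of the Bmp pathway, 3 of 12 of Fgf response, 2 of 12 of Wnt response, 3 of 13 of cartilage, 1 of 7 of tendon and 1 of 18 of the cell cycle, with 0 higher in each. Adjusted over the list alone, the higher and lower counts were 1 and 3, 3 and 3, 0 and 2, 1 and 3, 1 and 2, and 1 and 1. In the proximal and retinoic acid list 3 were higher and 3 lower of 14, and among the neighbours of Pitx1 1 and 1 of 7, with 3 and 3 and 2 and 1 adjusted over the list alone. No gene passed among the 12 endothelial, 7 nerve and Schwann, 14 surface ectoderm, 8 macrophage, 6 somite and trunk and 9 immediate early genes. Adjusted over the list alone, 2 higher and 2 lower surface ectoderm genes and 2 higher and 1 lower trunk genes passed, and 0 in the other 4 lists. Without forelimb replicate 2, the endothelial list (0.0156) and the macrophage list (0.00773) passed, both towards higher values in hindlimb, and so did the macrophage list without hindlimb replicate 2 (0.0241). The Bmp list passed towards lower values without forelimb replicate 1 (0.0402). Median, mean and test differed in sign for Fgf response (median 0.01, mean -0.04, test lower), proximal and retinoic acid genes (-0.02, 0.07, higher), tendon (0.04, -0.07, lower) and stage (-0.03, 0.11, higher).

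The CD1 count of 795 fell to 13 without the run term and was 471 with replicates 1 and 2 alone. It was 460 without forelimb replicate 3 and 394, 452 and 462 without hindlimb replicates 1, 2 and 3. The authors' deposited table called 1689 genes (643 higher and 1046 lower), among them all 795 with the same sign.

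The e11.0 comparison asked what changed in hindlimb buds that lack Pitx1. Tbx4 fell, as did the limb mesenchyme factors Tbx15, Tbx18 and Lhx9, Sox9 of cartilage, Scx of tendon and the muscle precursor genes Pax3, Lbx1 and Myf5. Of 13 cartilage genes 8 fell, while the tendon and muscle lists did not pass (camera adjusted p = 0.927 and 0.17). In the same libraries 10 of 12 endothelial genes fell and 6 of 14 surface ectoderm genes rose. The cartilage, endothelial and ectoderm lists did not pass with an estimated correlation (camera adjusted p = 0.661, 0.734 and 0.734), and when 1 library was left out these counts were 3 to 8, 0 to 11 and 1 to 13. By limma 1843 of 14027 genes changed, 664 higher and 1179 lower in null hindlimbs, and 40 of them by an absolute log2 fold change of at least 1 (12 higher and 28 lower). The balance of directions depended on scaling: the median log2 fold change of all genes was -0.073, and 1064 calls were higher and 524 lower after trimmed-mean scaling. After median-ratio scaling 1326 were higher and 403 lower, and after upper-quartile scaling 984 and 567. Of the 1843 calls, 1188, 1067 and 1231 were made again with the same sign after these 3 scalings.

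Pitx1 itself was at 124 ± 10.9 CPM in wild type and 21.2 ± 1.81 CPM in null hindlimbs (-2.50 ± 0.09, limma adjusted p = 3.12e-07), so reads were still counted on it in the null. Positions of reads within the gene are not given, so the source of these reads is not known. Which part of the gene the null allele lacks is not stated in the labels. Tbx4 fell from 66.0 ± 10.3 to 28.3 ± 4.33 CPM (-1.19 ± 0.11, adjusted p = 0.000295). Isl1 rose by 0.50 ± 0.11 (adjusted p = 0.0203), with overlap between the groups and a call in 4 of the 6 fits that left out 1 library. Hoxc10 fell by 0.43 ± 0.13 on the log2 scale (adjusted p = 0.0494), a call lost under each of the 3 scalings, and Hoxc11 did not pass (-0.36 ± 0.12, adjusted p = 0.0592, and 0.0223 with the replicate block). The hindlimb identity list held 2 higher and 3 lower of 8 genes, or 2 and 4 adjusted over the list alone, and did not pass (adjusted p = 0.376). Of 4 forelimb identity genes 1, Hoxc8, rose (0.33 ± 0.10), the same adjusted over the list alone, and the list did not pass (adjusted p = 0.889). Tbx5 was not among the genes listed at e11.0 or e11.5.

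Among the largest falls beside Pitx1 were AK157302 (-2.40 ± 0.16), an uncharacterised transcript, Zfp429 (-2.08 ± 0.14), of a zinc finger family whose similar copies can share reads, Sned1 (-1.48 ± 0.11), an extracellular matrix protein, and Asb4 (-1.32 ± 0.07), a ubiquitin ligase component. Nrk, a kinase, Abca8b, a transporter, and Evx1os, transcribed antisense beside Evx1, fell by 1.31, 1.28 and 1.28 on the log2 scale. Among the largest rises were Col14a1 (1.54 ± 0.17), a collagen of connective tissue, Sphkap (1.10), Corin (1.09), a membrane protease, Calb2 (1.03), a calcium-binding protein, Rxfp1 (1.0), Epha3 (1.0), an ephrin receptor, and Wnt2 (0.85), a secreted signal. Rxfp1, higher in CD1 hindlimb than forelimb, thus rose further, from 10.8 ± 0.945 to 22.6 ± 1.05 CPM.

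Of 18 limb patterning and connective tissue factors 9 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 0.000566, and adjusted p = 0.734 with an estimated correlation). Tbx15 fell from 109 ± 37.4 to 44.2 ± 12.9 CPM (-1.26 ± 0.08), Tbx18 by 1.04 and Lhx9 by 0.86 on the log2 scale, all genes of limb bud mesenchyme, and Emx2 rose (0.70 ± 0.09). Lin28b, also in the stage list, was 1 of the 9 that fell. Of 13 cartilage genes 8 fell and 0 rose, or 9 and 0 adjusted over the list alone (adjusted p = 0.000566, and adjusted p = 0.661 with an estimated correlation). Sox9, the main factor of cartilage precursors, fell from 25.9 ± 4.04 to 13.2 ± 1.62 CPM (-0.92 ± 0.10), with its partner Sox5 (-0.56) and Col9a1 (-0.59), a cartilage collagen. In the Shh pathway 5 of 12 genes fell, or 7 adjusted over the list alone (adjusted p = 0.00391, and adjusted p = 0.734 with an estimated correlation), led by the co-receptors Cdon (-0.76 ± 0.09) and Boc (-0.73 ± 0.09). Without wild type replicate 1, wild type replicate 3 or null replicate 3, the patterning list held 3, 5 and 5 lower genes, the cartilage list 3, 3 and 3 and the Shh list 2, 2 and 2, and the cartilage list held 5 and 3 without null replicates 1 and 2. Hoxa13 fell (-0.90 ± 0.16), the only call among 10 posterior HoxA and HoxD genes (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.459). Scx, the early tendon factor, fell from 25.2 ± 2.55 to 11.9 ± 1.56 CPM (-1.03 ± 0.11), while Postn, a matrix protein of the same list, rose (0.78 ± 0.12), and the tendon list with 1 higher and 3 lower of 8 did not pass, also 1 and 3 adjusted over the list alone (adjusted p = 0.927). Among muscle precursor genes Pax3 (-1.13 ± 0.13), Lbx1 (-1.01 ± 0.19) and Myf5 (-0.81 ± 0.13) fell and Des rose, 3 lower and 1 higher of 6, or 4 and 1 adjusted over the list alone (adjusted p = 0.17, and 0.0122 without null replicate 2).

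These falls came with shifts in markers of other cells. Of 12 endothelial genes 10 fell, or 11 adjusted over the list alone (adjusted p = 0.000205, and adjusted p = 0.734 with an estimated correlation), with Kdr, a Vegf receptor, at -0.66 ± 0.13 and Cdh5, an adhesion protein of vessels, at -0.68 ± 0.15. After the 3 scalings 6, 4 and 6 endothelial genes still fell, and 7, 5 and 7 cartilage genes. Without wild type replicates 1, 2 and 3, 0, 11 and 0 endothelial genes were called, and without null replicates 1, 2 and 3, 7, 1 and 0. Of 14 surface ectoderm genes 6 rose, or 7 adjusted over the list alone (adjusted p = 2.15e-07, and adjusted p = 0.734 with an estimated correlation), among them Wnt7a (0.63 ± 0.09), the dorsal ectoderm signal, and Krt18 and Krt5, keratins, at 0.39 each. Without wild type replicates 1, 2 and 3, 1, 13 and 1 surface ectoderm genes were called, and without null replicates 1, 2 and 3, 2, 1 and 1. Levels of Krt5 varied between libraries of a group, at 54.9 ± 38.2 CPM in wild type. In the erythroid list 1 of 14 genes, Hbb-bs, rose (11 without wild type replicate 2, and 0 without wild type replicate 1 or 3 or null replicate 2 or 3), the same adjusted over the list alone (adjusted p = 0.00631, and adjusted p = 0.805 with an estimated correlation). The erythroid list did not pass without replicate 3 of either group (0.776 and 0.777) or without wild type replicate 1 (0.0666), nor without globin, mitochondrial and abundant noncoding genes (0.24).

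The ridge list passed towards higher values, with 2 higher and 1 lower of 14 (4 and 1 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.734 with an estimated correlation). Its higher members were Wnt3 (0.38 ± 0.09) and Sp8 (0.28 ± 0.08), and its lower member Cd44 was lost under all 3 scalings. The ridge list held 6 higher genes without wild type replicate 2 and 0 without any other library. It did not pass after median-ratio scaling (0.051) or without replicate 1 of wild type (0.0781) or null (0.065). Among anterior Hox genes Hoxb2 (0.77 ± 0.11) and Hoxb4 (0.41 ± 0.11) rose, 2 of 17, the same adjusted over the list alone (adjusted p = 0.0241, and adjusted p = 0.734 with an estimated correlation). It held 4 higher genes with the replicate block or without wild type replicate 2, and 1 without any other library. This list did not pass after trimmed-mean scaling (0.051), median-ratio scaling (0.0638) or without wild type replicate 2 (0.164). Of the 7 stage genes Lin28a (-0.68 ± 0.14) and Lin28b (-0.30 ± 0.07) fell, or 4 adjusted over the list alone (adjusted p = 0.0263, and adjusted p = 0.734 with an estimated correlation). In the nerve and Schwann list 1 of 7 genes, Nefl, a neurofilament, rose, the same adjusted over the list alone (adjusted p = 0.0406, and adjusted p = 0.734 with an estimated correlation). With the replicate block 4 stage and 2 nerve genes were called. Without wild type replicates 1, 2 and 3 the stage list held 0, 6 and 1 lower genes and the nerve list 0, 2 and 0 higher genes, and without null replicates 1, 2 and 3 they held 1, 0 and 1, and 1, 1 and 0. The stage and nerve lists did not pass without wild type replicate 1 (0.0538 and 0.0841), wild type replicate 3 (0.0623 and 0.0623) or null replicate 3 (0.0644 and 0.0644). The nerve list was also lost under each scaling (0.0684, 0.0911 and 0.0653). The other lists did not pass, with adjusted p from 0.259 to 0.93. They held, as higher and lower genes, 0 and 1 of 12 for the Bmp pathway, 0 and 3 of 12 for Fgf response, 1 and 1 of 11 for Wnt response and 2 and 1 of 14 for proximal and retinoic acid genes. Adjusted over the list alone, these were 0 and 1, 0 and 3, 1 and 4, and 2 and 3. Further counts were 2 and 3 of 8 for anterior mesenchyme, 1 and 2 of 6 for somite and trunk, 2 and 0 of 18 for the cell cycle and 1 and 2 of 8 for the neighbours of Pitx1. Adjusted over the list alone, they were 2 and 3, 1 and 2, 2 and 3, and 1 and 2. No gene passed, by either adjustment, among 9 macrophage, 11 hypoxia and glycolysis, 9 immediate early and 5 sex genes. With the replicate block limma called Ddx3y (0.42, adjusted p = 0.0067) higher, and Xist (-0.38, 0.0181) and Btg2 (-0.35, 0.0396) lower. The authors' deposited edgeR adjusted p called the Y-linked Ddx3y (0.00423), Eif2s3y (0.00912) and Uty (0.02) higher, but not Xist (0.983). Whether embryo sex was balanced at e11.0 is thus not settled. The anterior mesenchyme list passed without null replicate 2 (0.0356) and the sex list without wild type replicate 1 (0.00323). The tests pointed to higher values against a negative median and mean for forelimb identity (-0.08, -0.02), proximal and retinoic acid (-0.02, -0.02), macrophage (-0.05, -0.05) and hypoxia genes (-0.01, -0.01). The tendon list had a median of 0.09, a mean of -0.11 and a test towards lower values.

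The e11.0 count of 1843 was 3442 (1056 higher and 2386 lower) with the replicate block, 5 without the run term and 199 with replicates 1 and 2 alone. It was 116, 5273 and 193 without wild type replicates 1, 2 and 3, and 1032, 232 and 196 without null replicates 1, 2 and 3. The authors' deposited table called 2895 genes (1707 higher and 1188 lower), and the 1626 called by both had the same sign. Of 78 named genes called, 29 were called in all 6 fits that left out 1 library, among them Pitx1, Tbx4, Tbx15, Sox9, Scx and Pax3. Isl1 and Myf5 were called in 4 of these 6 fits, and Lbx1 and Hoxa13 in 3. The fits without replicate 3 of either group rest on the same comparison of replicates 1 and 2.

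The e11.5 comparison asked the same of older hindlimb buds, in which cartilage condensations form. Of 16 cartilage, 11 muscle and 8 tendon genes 14, 9 and 4 fell in null hindlimbs, and Tbx4 fell again. Of 18 cell cycle genes 7 rose, with 5 of 12 of the Bmp pathway and 5 of 17 anterior Hox genes, all of the HoxB cluster. None of these lists passed with an estimated correlation (camera adjusted p = 0.207 to 0.562), and when 1 library was left out the cell cycle and anterior Hox counts were 0 to 9 and 2 to 8. By limma 1455 of 13478 genes changed, 382 higher and 1073 lower in null hindlimbs, and 56 of them by an absolute log2 fold change of at least 1 (6 higher and 50 lower). The split was 691 higher and 917 lower after trimmed-mean scaling and 743 and 919 after median-ratio scaling.

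Pitx1 was at 338 ± 23.7 CPM in wild type and 79.8 ± 8.31 CPM in null hindlimbs (-2.07 ± 0.05, limma adjusted p = 1.87e-07). Tbx4 fell from 189 ± 26.9 to 80.5 ± 14.1 CPM (-1.23 ± 0.05, adjusted p = 1.01e-05). The other measured hindlimb identity genes did not pass, among them Isl1 at -0.20 ± 0.08, Hoxc10 at -0.10 ± 0.06 and Hoxc11 at -0.06 ± 0.06. The list of 8 thus held 2 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.00922, and adjusted p = 0.436 with an estimated correlation), and its lower members include the mutated gene itself. None of 4 forelimb identity genes passed by limma, at either adjustment (list adjusted p = 0.744), where 4043 of all genes had an unadjusted p under 0.05.

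Of 16 measured cartilage genes 14 fell and 0 rose, the same adjusted over the list alone (adjusted p = 2.97e-14, and adjusted p = 0.207 with an estimated correlation). Matn4, a cartilage matrix protein, fell from 8.39 ± 1.58 to 0.398 ± 0.172 CPM (-2.74 ± 0.11, limma adjusted p = 9.82e-06), and Cnmd, chondromodulin, from 3.48 ± 0.977 to 0.240 ± 0.137 CPM (-1.83 ± 0.11). The collagens Col9a3 (-1.75 ± 0.14), Col9a2 (-1.73 ± 0.16) and Col2a1 (-1.12 ± 0.06), the main collagen of cartilage, fell, Col2a1 from 610 ± 75 to 280 ± 18.6 CPM. Of 11 muscle genes 9 fell and 1 rose, the same adjusted over the list alone (adjusted p = 4.93e-05, and adjusted p = 0.207 with an estimated correlation). Myod1, a factor that commits cells to muscle, fell from 7.93 ± 2.48 to 2.51 ± 1.54 CPM (-1.42 ± 0.15), with Msc (-1.16 ± 0.12), Actc1 (-0.96 ± 0.14), an actin, and Met (-0.58 ± 0.05), the receptor used by migrating precursors. Of 8 tendon genes 4 fell, or 5 adjusted over the list alone (adjusted p = 0.000435, and adjusted p = 0.491 with an estimated correlation), with Tnc at -1.13 ± 0.10, Scx at -0.91 ± 0.16 and Mkx at -0.75 ± 0.10. Further large falls were Dab1 (-1.65 ± 0.10), an adaptor of Reelin signalling, Nfatc2 (-1.82 ± 0.20), a transcription factor, and AK157302 (-2.38 ± 0.11). Surface ectoderm markers moved with these groups: 2 of 14, Wnt7a (0.59 ± 0.08) and Cldn6 (0.39 ± 0.09), rose, or 7 adjusted over the list alone (adjusted p = 8.74e-05, and adjusted p = 0.562 with an estimated correlation). They numbered 4 without wild type replicate 1, and 1 without wild type replicate 2 or 3 or null replicate 2 or 3. Macrophage markers moved as well, with C1qa (-0.45 ± 0.12) and Csf1r (-0.45 ± 0.12) lower, 2 of 11 by both adjustments (adjusted p = 0.0482, and adjusted p = 0.621 with an estimated correlation). The macrophage list held 0 lower genes without wild type replicate 2 or 3 or any 1 of the null libraries, and did not pass without replicate 2 (0.199) or 3 (0.0663) of wild type or replicate 1 (0.232) or 3 (0.0671) of null.

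**Figure D3:**
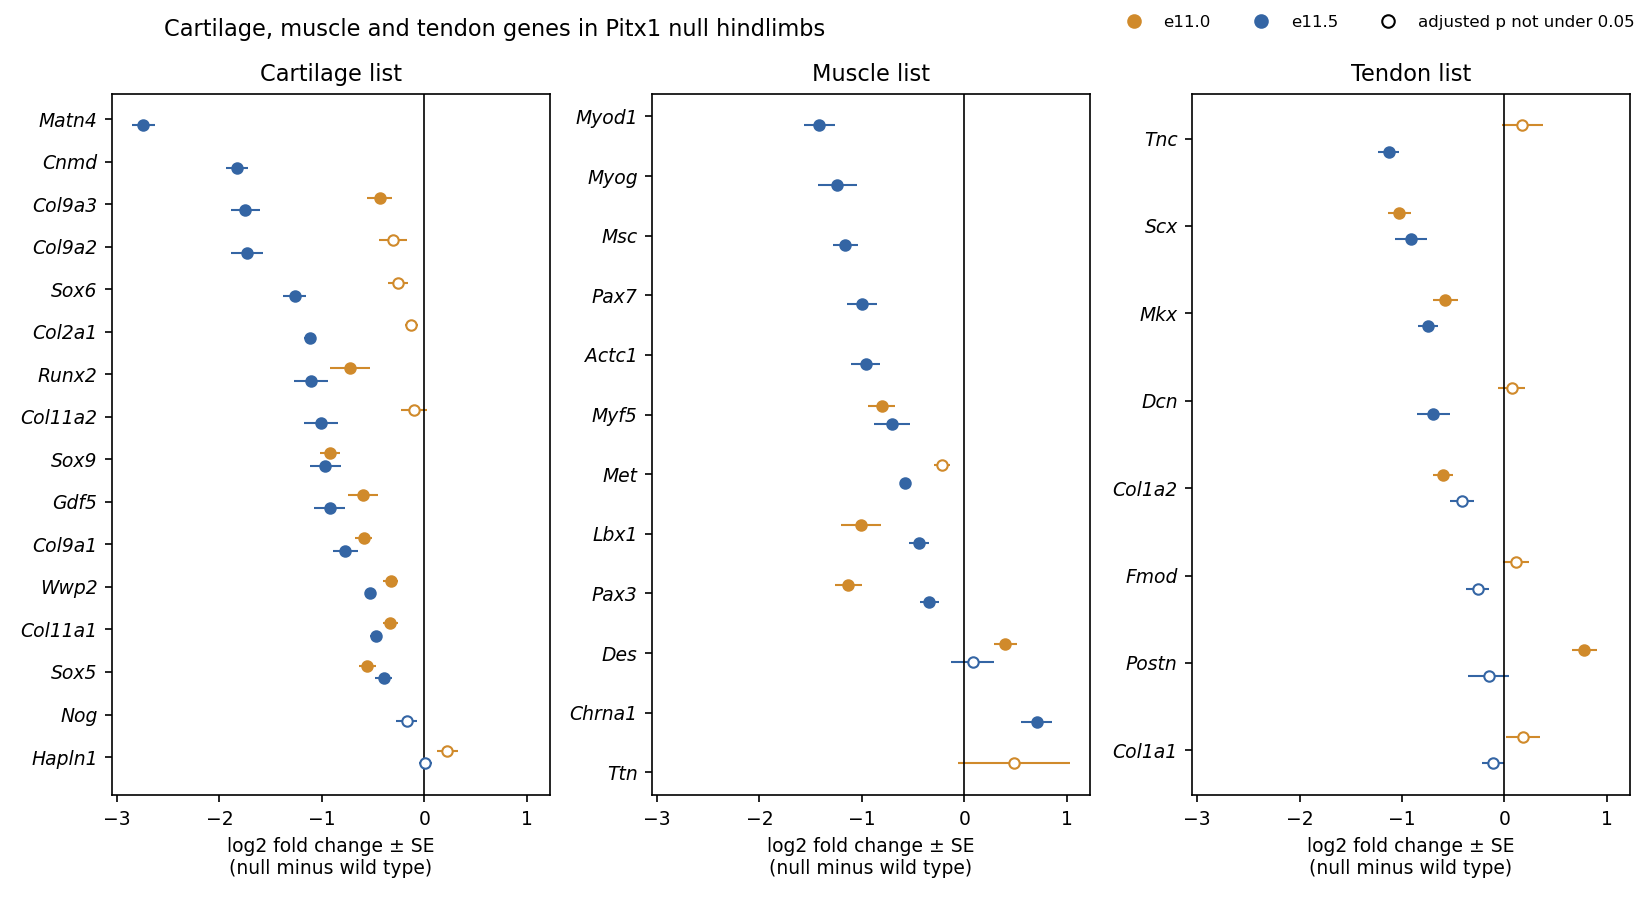
Log2 fold change (null minus wild type, points, bars for SE, 3 libraries per group) of the measured cartilage, muscle and tendon genes at e11.0 and e11.5, with open points for genes that did not pass; a missing point means that the gene is not listed at that stage. At e11.5 Matn4 lay at -2.74 and Col2a1 at -1.12, and Sox9 lay at -0.92 at e11.0 and -0.97 at e11.5.

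Among genes that rose, Gbx2, a homeobox factor, went from 1.84 ± 0.405 to 7.91 ± 1.25 CPM (1.65 ± 0.12, limma adjusted p = 0.000164) and Vegfd, a lymphatic growth factor, from 3.45 ± 0.524 to 10.8 ± 1.79 CPM (1.41 ± 0.09). Rab6b (1.02), Gpx2 (1.0), a glutathione peroxidase, Dkk1 (0.92), a Wnt antagonist, Tfap2c (0.82), an ectodermal factor, and Bhlha9 (0.77), a ridge factor, rose too. Of 12 genes of the Bmp pathway 5 rose and 0 fell, or 5 and 1 adjusted over the list alone (adjusted p = 8.74e-05, and adjusted p = 0.491 with an estimated correlation), among them the ligands Bmp7 (0.47 ± 0.05) and Bmp4 (0.37 ± 0.05) and their target Id1 (0.47 ± 0.07). Of 18 cell cycle genes 7 rose, or 9 adjusted over the list alone (adjusted p = 6.17e-06, and adjusted p = 0.207 with an estimated correlation), by small amounts such as 0.23 ± 0.05 for Cdk1 and 0.20 ± 0.05 for Pcna. Without wild type replicates 1, 2 and 3 these numbered 2, 0 and 0, and without null replicates 1, 2 and 3 9, 0 and 0. Of 17 anterior Hox genes 5 rose, or 6 adjusted over the list alone (adjusted p = 0.000152, and adjusted p = 0.562 with an estimated correlation), with Hoxb6 at 0.72 ± 0.12, Hoxb2 at 0.64 ± 0.10 and Hoxb3 at 0.52 ± 0.08. They numbered 8 without null replicate 1, 2 without null replicate 2 and 3 without replicate 3 of either group. In the Fgf response list 4 of 12 rose, Fgf10 (0.65 ± 0.07), the mesenchymal signal of outgrowth, Spry4, Spry1 and Etv4, and 2 fell (5 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.0694). It passed without wild type replicate 1 (0.0406) or null replicate 2 (0.0333).

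Wnt response genes passed with 4 higher and 1 lower of 12, or 5 and 1 adjusted over the list alone (adjusted p = 0.0415, and adjusted p = 0.436 with an estimated correlation), with Axin2 at 0.27 ± 0.05. This was lost after trimmed-mean (0.0591) and median-ratio (0.0597) scaling and without null replicate 1 (0.147). The higher genes numbered 2 without wild type replicate 2 or replicate 3 of either group, and 1 without null replicate 2. Posterior HoxA and HoxD genes passed with 3 higher, Hoxa11 (0.46 ± 0.06), Hoxd11 (0.41 ± 0.07) and Hoxd10 (0.34 ± 0.07), and 1 lower, Evx2 (-0.75 ± 0.20, not called with the replicate block, adjusted p = 0.0551), of 10, or 4 and 2 adjusted over the list alone (adjusted p = 0.0482, and adjusted p = 0.621 with an estimated correlation). That list was lost after trimmed-mean (0.0794) and median-ratio (0.0823) scaling and without wild type replicate 2 (0.131) or null replicate 1 (0.214). It held 1 higher gene without null replicate 2, and 2 lower without null replicate 1 and 0 without wild type replicate 1, null replicate 2 or replicate 3 of either group. In the ridge list Sp8 rose (0.33 ± 0.08) and Fgf9 (-0.71 ± 0.14) and Cd44 (-0.29 ± 0.08, not called with the replicate block, adjusted p = 0.0534) fell, 3 of 14, or 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.0496 towards higher values, and adjusted p = 0.562 with an estimated correlation). The ridge list was lost under each scaling (0.0867, 0.0917 and 0.0523), with the replicate block (0.0562), and without wild type replicate 2 (0.128) or null replicates 1 (0.123) or 2 (0.0697). Without wild type replicates 1, 2 and 3 it held 2, 0 and 1 higher and 1, 1 and 0 lower genes, and without null replicates 1, 2 and 3 it held 2, 0 and 1 higher and 1, 0 and 0 lower. The other lists did not pass, with adjusted p from 0.0602 to 0.8. They held, as higher and lower genes, 2 and 3 of 12 for the Shh pathway, 1 and 1 of 14 for proximal and retinoic acid genes, 3 and 3 of 9 for anterior mesenchyme, and 4 and 2 of 18 for limb patterning factors. Adjusted over the list alone, these were 3 and 4, 1 and 1, 3 and 3, and 6 and 4. In the patterning list Tbx18 (-0.99 ± 0.12) and Tbx15 (-0.69 ± 0.09) fell and Prrx2 (0.37 ± 0.04) and Sall3 (0.42 ± 0.05) rose, and in the anterior list Pax9, a paired-box factor, fell (-1.44 ± 0.15). Further counts were 0 and 2 of 12 for endothelium, 0 and 2 of 9 for nerve and Schwann cells, 0 and 1 of 6 for somite and trunk, 1 and 1 of 11 for hypoxia and glycolysis, 2 and 2 of 8 for immediate early genes and 0 and 2 of 9 for the neighbours of Pitx1. Adjusted over the list alone, they were 0 and 2, 0 and 2, 0 and 2, 3 and 3, 2 and 2, and 0 and 3. No gene passed, by either adjustment, among 14 erythroid, 7 stage and 5 sex genes. The Y-linked Kdm5d, Eif2s3y, Ddx3y and Uty were nonetheless at -0.92, -0.78, -0.76 and -0.67 (limma adjusted p = 0.23 to 0.446), and Xist at -0.22 (0.95). The authors' deposited edgeR adjusted p called Kdm5d (0.00139), Ddx3y (0.00858) and Uty (0.0139) lower in null hindlimbs, but not Eif2s3y (0.36). Whether embryo sex was balanced between the groups is thus not settled. The endothelial list passed towards lower values with the replicate block (0.039) and without replicate 3 of either group (0.00684 and 0.00733) or null replicate 2 (0.0104). The erythroid (0.0366) and trunk (0.0366) lists passed without wild type replicate 1, and the trunk (0.0374) and Pitx1 neighbour (0.0482) lists without null replicate 2. For anterior mesenchyme (median 0.01, mean -0.09) and limb patterning factors (0.03, -0.01) the mean was negative while median and test pointed to higher values.

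The e11.5 count of 1455 was 11 without the run term and 483 with replicates 1 and 2 alone. It was 784 and 465 without wild type replicates 2 and 3, and 2627, 433 and 471 without null replicates 1, 2 and 3. The authors' deposited table called 2644 genes (1176 higher and 1468 lower), and the 1435 called by both had the same sign. Of 82 named genes called, 43 were called in all 6 fits that left out 1 library, among them Pitx1, Tbx4, Matn4, Col2a1, Myod1, Gbx2 and Scx. As at e11.0, the fits without replicate 3 of either group were not separate from each other.

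The genes that changed at e11.0 and at e11.5 overlapped. Of 12935 genes in both tables, 351 fell at both stages, against 86.9 for independent lists of 1172 and 959 genes (odds ratio 7.84, 95% interval 6.73 to 9.13, Fisher's exact p = 2.28e-136). Rises at both stages numbered 113, against 18.2 for lists of 622 and 379 (odds ratio 10, interval 7.85 to 12.8, Fisher's exact p = 6.67e-60), and genes are not independent replicates. Of 474 genes called at both stages 464, or 97.9%, had the same sign, and fold changes correlated with r = 0.49 across genes. Pitx1, Tbx4, Sox9, Scx, Tbx15, Tbx18, Asb4, Cdon and Boc fell at both stages, and Wnt7a, Hoxb2 and Dkk1 rose at both. The 10 genes called with opposite signs included Aldh1a2, the retinoic acid synthase, at 0.63 ± 0.16 at e11.0 and -1.06 ± 0.25 at e11.5, and Msx1, a Bmp target, at -0.40 ± 0.10 and 0.30 ± 0.05. Grem1, a Bmp antagonist, was at -0.38 ± 0.09 and 0.40 ± 0.05. Under the 3 scalings Aldh1a2, Msx1 and Grem1 were called at both stages in 3, 1 and 2, and at e11.0 they were called in 4, 2 and 2 of the 6 fits that left out 1 library (2, 4 and 6 at e11.5). Whether the effects at these stages differ was not tested, for these or any genes. Stage and library type (ribosomal RNA depletion at e11.0, mRNA enrichment at e11.5) changed together and cannot be told apart. Fold changes also fell with the merged length of a gene's annotated exons at both stages (Spearman rho -0.308 and -0.231). The overlap thus does not measure shared Pitx1 effects alone. The shared falls numbered 203 and the shared rises 223 after trimmed-mean scaling, 184 and 262 after median-ratio scaling, and 65 and 11 with replicates 1 and 2 alone. Leaving out 1 library gave 62 (without e11.0 wild type replicate 1) to 527 shared falls and 16 (without e11.5 null replicate 2) to 227 shared rises.

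**Figure D4:**
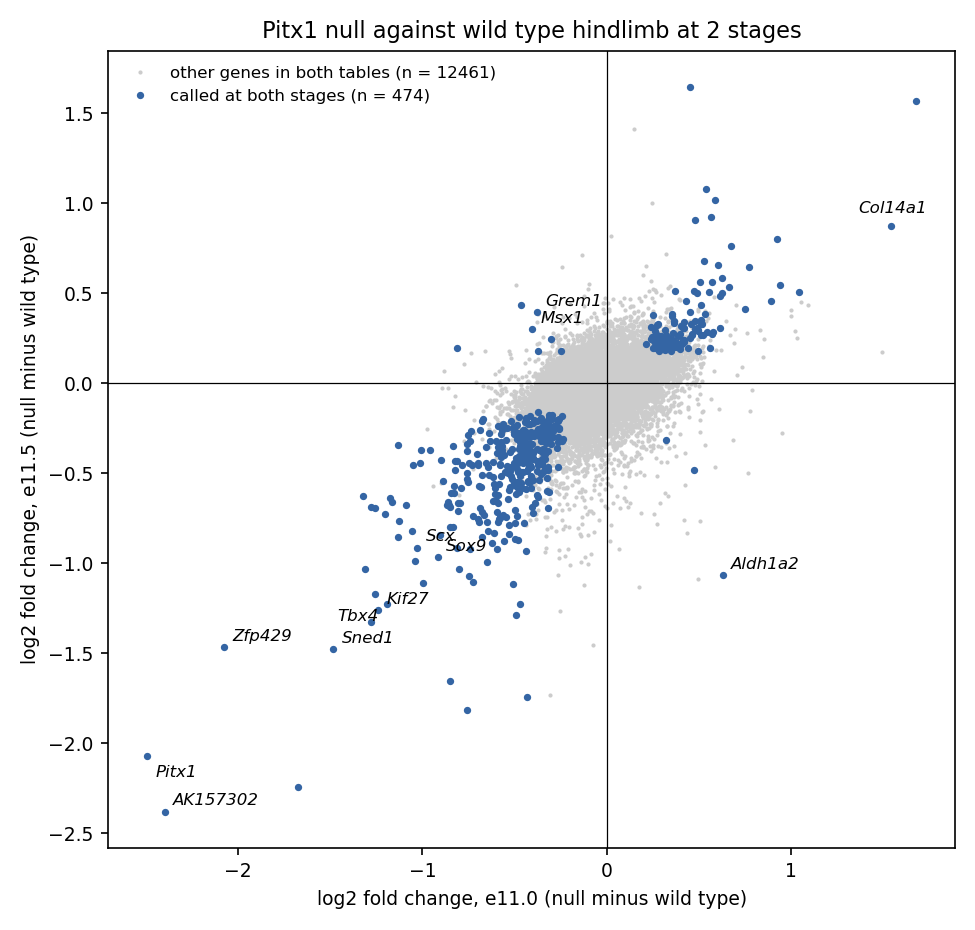
Log2 fold change (null minus wild type) at e11.5 against that at e11.0 for 12935 genes in both tables, with blue points for the 474 genes called at both stages and grey points for the rest, from 3 libraries per group. Pitx1 and Tbx4 lie in the lower left quadrant, at -2.50 and -1.19 at e11.0, and Aldh1a2 in the lower right, at 0.63 and -1.06.

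The limb-type sets asked how genes that differ between hindlimb and forelimb behave without Pitx1. They rest on the CD1 comparison and so can hold differences of embryo age, and the hindlimb-higher set includes the globins Hbb-bs and Hbb-bt. Of the 28 genes of the hindlimb-higher set 26 were measured at e11.0, where 12 fell and 6 rose, and the set did not pass (camera p = 0.188, and p = 0.369 with an estimated correlation). Tbx4, Hoxa13, Evx1os and Hoxc10 were among those that fell, and Rxfp1, Isl1, Aldh1a2, Wnt2 and Hbb-bs among those that rose. The set passed towards lower values after trimmed-mean (0.0384), median-ratio (0.0167) and upper-quartile (0.0394) scaling and without null replicate 1 (0.0382). At e11.5, 8 of 27 fell and 0 rose (p = 0.000219, and p = 0.0865 with an estimated correlation), among them Tbx4, Aldh1a2 and Evx1os. Of the 46 genes of the forelimb-higher set 34 were measured at e11.0, where 7 rose, among them Hoxb2, Hoxb4, Epha3, Gria2 and Alx1, and 3 fell, Runx2, Sim2 and Rspo4 (p = 0.00396 towards higher values, and p = 0.19 with an estimated correlation). Sim2 was named after its values were seen. At e11.5, 5 of 38 rose and 9 fell, and the set did not pass (camera p = 0.894 at the preset correlation). Overlaps with calls, by Fisher's exact test, were larger than for independent sets in both directions for the hindlimb-higher set at e11.0 (lower, odds ratio 8.93, p = 6.33e-07; higher, 6.02, p = 0.00118) and for the forelimb-higher set at e11.5 (lower, 3.81, p = 0.00175; higher, 5.12, p = 0.00457). The same exact test gave 5.16 (p = 0.000643) for hindlimb-higher genes that fell at e11.5 and 5.21 (p = 0.000957) for forelimb-higher genes that rose at e11.0. With no limit on the CD1 fold change this set turned towards lower values, at p = 0.273 for e11.0 and p = 0.00464 for e11.5 by camera at the preset correlation.

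Genes near Pitx1 were examined because a null allele bred into another strain can carry linked variants. Within 20 Mb on either side 34 of 233 genes changed at e11.0 (14.6%, against 13.1% elsewhere; odds ratio 1.13, Fisher's exact p = 0.494) and 29 of 230 at e11.5 (12.6%, against 10.8%; odds ratio 1.20, p = 0.39, exact). Within 5 Mb 18 of 75 changed at e11.0 (odds ratio 2.10, Fisher's exact p = 0.00926) and 14 of 74 at e11.5 (odds ratio 1.94, Fisher's exact p = 0.036), against 8 of 71 in CD1, where no Pitx1 allele was compared (odds ratio 2.05, Fisher's exact p = 0.0692). The e11.0 odds ratio over 20 Mb was 1.49 after trimmed-mean scaling, 2.90 with replicates 1 and 2 alone and between 0.988 (without wild type replicate 2) and 3.95 (without wild type replicate 1) when 1 library was left out.

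**Figure D5:**
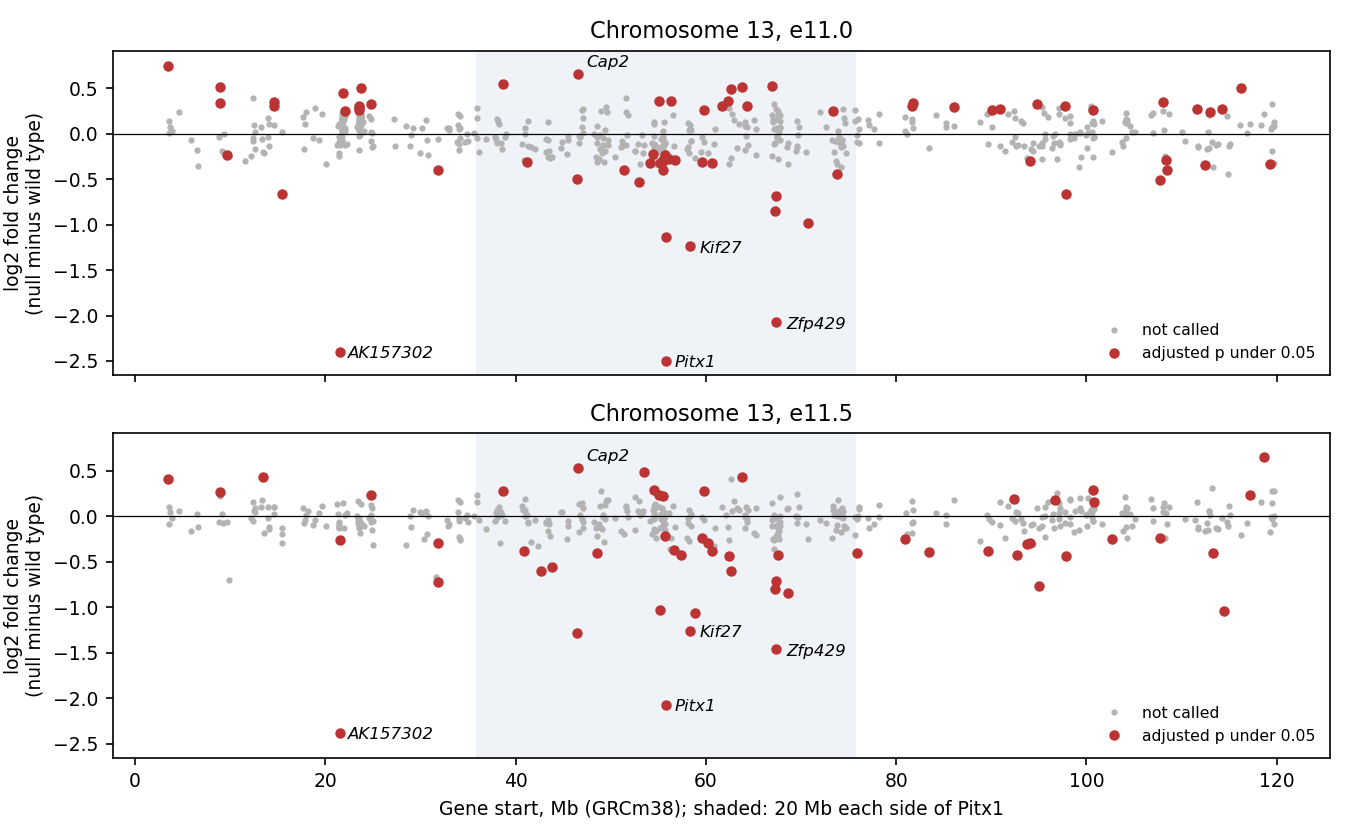
Log2 fold change (null minus wild type, 3 libraries per group) of the genes listed on chromosome 13 at e11.0 (top) and e11.5 (bottom) against gene start in Mb (GRCm38), with red points for genes called and the 20 Mb on either side of Pitx1 shaded. AK157302, at 21.5 Mb, lay at -2.40 and -2.38, and Zfp429, at 67.4 Mb, at -2.08 and -1.46.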

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

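The length test below was written before the results were seen, and the other tests here were chosen after. At e11.0 calls were 664 higher and 1179 lower with the deposited CPM, against 1326 and 403 after median-ratio scaling. Fold changes fell with the merged length of a gene's annotated exons across genes (Spearman rho -0.308 at e11.0). A difference in RNA integrity or fragment selection between the groups may thus contribute, though this length is not that of the transcripts expressed. The same trend was present in CD1 (-0.25) and e11.5 (-0.231). In CD1 the split of calls did not turn, with 326 higher and 469 lower against 323 and 535 after median-ratio scaling. The median of all CD1 genes was 0.006 with the deposited CPM, so CD1 cannot tell whether a length trend turns the split. The trend was present in every comparison, but its size in long genes differed. The longest 20% of genes had a median of -0.15 at e11.0, against -0.05 in CD1 and -0.08 at e11.5. The shortest 20% had medians of 0.05, 0.06 and 0.03. A length effect on the e11.0 split thus stays open. Abundant RNAs taking more of the counts stay open. The median of -0.073 became -0.061 (702 genes higher and 938 lower) without the 20 most abundant genes, -0.049 (726 and 749) without 100 and -0.028 (764 and 540) without 500. Another amount of RNA per cell stays open too, with the 500 most abundant genes at a median of 0.07 and no spike-in.

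The tests of the genes on chromosome 13 were chosen after results were seen, as were the genes Kif27, Cap2, Zfp458 and Zfp459. AK157302, Zfp429 and Kif27 (-1.24 and -1.26) fell at e11.0 and e11.5, and Cap2 rose (0.66 and 0.54). That Pitx1 raises Kif27, Zfp429, Zfp458 and Zfp459 in any limb bud was argued against by a median of -0.06 between CD1 hindlimb and forelimb over these 4 genes. This holds only if embryo age, which changes with limb type there, and the other strain do not hide such an effect. Zfp429, Zfp458 and Zfp459 lie together at 67.3 to 67.4 Mb and may share reads, so they are not separate evidence. For AK157302 the same account stays open, since it is not listed in CD1 and 0 CD1 libraries have a value for it. Every gene listed there exceeded 0.5 CPM in at least 3 libraries, so AK157302 may have been below that level in CD1 hindlimb. It was at 4.87 and 4.56 CPM in wild type hindlimbs at e11.0 and e11.5. A level that low in CD1 hindlimb would go against the account, but the rule for listing genes was not stated. Variants linked to the null allele stay open for all of these genes. Pitx1 and genes without coordinates were left out of this count. Of the remaining 463 genes called the same way at both stages 21 lay on chromosome 13, against 447 of 12457 other genes (odds ratio 1.28, 95% interval 0.774 to 2, Fisher's exact p = 0.309). With an absolute log2 fold change of at least 0.5 they were 6 of 109 (odds ratio 1.56, Fisher's exact p = 0.294). With at least 1 they were 3 of 10, against 465 of 12910 (odds ratio with a 95% interval of 1.91 to 50.4, Fisher's exact p = 0.00468), but those 3, AK157302, Zfp429 and Kif27, are the genes that prompted the test, so it does not support linked variants.

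The tests of the falls of cartilage and muscle genes at e11.5 were chosen after results were seen. In the same libraries 2 of 14 surface ectoderm genes were called higher (camera adjusted p = 8.74e-05, and adjusted p = 0.562 with an estimated correlation). A larger share of surface ectoderm in null limb buds could dilute the mesenchyme. At e11.5 the limb patterning list kept a median of 0.03, against -0.99 for cartilage, which argues against dilution as the whole account of the e11.5 falls. This list is a limited gauge of mesenchyme, since 4 of its 18 genes rose and 2 fell. At e11.0 its median was -0.35, with cartilage at -0.33 and surface ectoderm at 0.24, so dilution stays open there. That the null hindlimbs are at an earlier stage could also delay cartilage and muscle, and the stage list, at a median of 0.07, leaves this open.

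Il17rd, an Fgf antagonist, Msx1 and Aurka, a mitotic kinase, chosen after results were seen, had every null library on one side of every wild type library at e11.0 and on the other side at e11.5. Their log2 fold changes were -0.52 and 0.14, -0.4 and 0.3, and -0.26 and 0.21, and the difference was not tested. Il17rd did not pass at e11.5 (adjusted p = 0.033 at e11.0 and 0.0967 at e11.5) and Aurka did not pass at e11.0 (0.0567 and 0.0175), where it passed with the replicate block (0.019).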

How the results depend on the processing

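The counts of called genes depended on the run term, on the limits on adjusted p and fold change, and on single libraries, and the cause was not tested. Without the run term they were 13 (CD1), 5 (e11.0) and 11 (e11.5), with replicates 1 and 2 alone 471, 199 and 483, at adjusted p under 0.01 394, 200 and 414, and with an absolute log2 fold change of at least 1 75, 40 and 56. With the replicate block they were 640, 3442 and 1437. The block ended 4 of 69, 0 of 78 and 3 of 82 calls of named genes and added 2, 17 and 3, and it changed no other call of a named gene. The authors' deposited adjusted p gave 1689, 2895 and 2644. Leaving out 1 library gave 394 to 1191, 116 to 5273 and 433 to 2627 genes, and 9 to 12, 7 to 12 and 8 to 15 lists. Among these fits, those without replicate 3 of either group repeat the comparison of replicates 1 and 2 alone. With an estimated correlation 0, 0 and 0 lists were called. By camera at the preset correlation, the hindlimb-higher set at e11.0 had p = 0.0384, 0.0167 and 0.0394 after trimmed-mean, median-ratio and upper-quartile scaling, 0.0313 without abundant noncoding, mitochondrial and globin genes, 0.0189 without the run term, 0.00255 with no fold limit, and 0.0382 to 0.478 with 1 library left out. The forelimb-higher set at e11.0 had 0.19 with an estimated correlation, 0.273 in the other direction with no fold limit, 0.274 at a limit of 2, and 2.32e-05 to 0.0273 with 1 library left out. At e11.5 the hindlimb-higher set had 0.0865 with an estimated correlation, 0.22 at a limit of 2 and 6.81e-05 to 0.000952 with 1 library left out, and the forelimb-higher set 0.00464 in the other direction with no fold limit and 0.466 to 0.977. Shared falls numbered 203 (trimmed-mean), 184 (median-ratio), 62 (adjusted p under 0.01), 2 (no run term), 65 (replicates 1 and 2) and 62 to 527 (1 library left out), and shared rises 223, 262, 10, 1, 11 and 16 to 227, with 440 by the authors' deposited adjusted p. The odds ratio near Pitx1 at e11.0 was 1.49 (trimmed-mean), 1.48 (upper-quartile), 2.89 (adjusted p under 0.01), 2.9 (replicates 1 and 2), 2.1 (5 Mb) and 0.988 to 3.95 (1 library left out), and at e11.5 2.19 (replicates 1 and 2), 1.94 (5 Mb) and 0.948 to 2.13. Called named genes that lost their call numbered 59 of 69, 74 of 78 and 77 of 82 without the run term, 11, 39 and 32 with replicates 1 and 2 alone, and 7, 12 and 6 at e11.0 after the 3 scalings. Keeping genes at 1 CPM or more in 3 libraries removed none. At most 0.0575 CPM was the worth of 1 read, and genes under 0.5 CPM are not listed; how depth limits the calls was not tested. DESeq2, a robust-dispersion likelihood-ratio test and limma-voom were planned for counts and were not run on CPM or on the reads implied by it, nor were other filters on low counts, since unlisted genes are absent, nor the difference between stages and its alternatives.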

Other observations

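The genes in this part were chosen after the results were seen, as were the split tests of gene calls, while those of lists and sets were chosen before. Pf4, a chemokine of platelets, was called with opposite signs at both stages (0.48 at e11.0 and -0.48 at e11.5), as was Sema3c, a guidance signal (0.32 and -0.32). Of the 6 fits that left out 1 library, Pf4 was called in 2 at e11.0 and 4 at e11.5, and Sema3c in 1 and 2. Runx2, lower in CD1 hindlimb than forelimb, fell in null hindlimbs at e11.0 (-0.72) and e11.5 (-1.1), while Alx1 rose by 0.57 at each. Lhx2, a factor of limb outgrowth, rose at e11.5 (0.65 ± 0.09).

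Each comparison has 10 splits of its 6 libraries into 3 and 3, which cannot give a share under 0.1. The real split called 795, 1843 and 1455 genes in CD1, e11.0 and e11.5, reached by 1, 1 and 1 of the 10 splits, with at most 6, 0 and 0 in another split. Every other split mixes the compared groups, so a group difference adds to its residual spread and lowers its calls. The low counts in other splits thus do not show that the calls of the real split are sound. The real split called 11, 10 and 12 lists, reached by 1, 3 and 3 splits, with at most 6, 10 and 13 in another. The other 3 splits that part all same-numbered libraries called 0 genes each, and 4, 2 and 1 lists in CD1, 6, 10 and 10 at e11.0 and 10, 5 and 6 at e11.5. By camera at the preset correlation, the hindlimb-higher set had p = 0.188 at e11.0 and 0.000219 at e11.5, matched by 4 and 1 splits (smallest other 0.00213 and 0.00307), and the forelimb-higher set 0.00396 and 0.894, matched by 4 and 9 (7.48e-08 and 0.0259).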
